A study of Drosophila melanogaster with 4 samples.

How the data were processed

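H3K4me3 was measured by chromatin immunoprecipitation and sequencing in white prepupae, in 2 immunoprecipitated and 2 input libraries, per the labels. The submitters' processing notes name CASAVA (versions 1.7.0.2 and 1.7.0.3), BWA, MACS2 and the BDGP5 assembly, without versions for BWA and MACS2 and without their settings. The deposited file is 1 list of peaks for the series, per the file headers on FlyBase release 5, with the arm, start, end and a score for each peak. The score was deposited by the authors without the name of its scale, so it was used only to rank, filter and describe peaks within the list, and a difference in score is in the caller's own unit. Whether the replicates were pooled before calling, and how the input libraries entered the call, is not given in the sources used here. The list carries no read counts and no values per library, so the depth of each library and the precision it gives are unknown, and none of the tests has a replicate as its unit.

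From the list, the width of each peak was taken as end minus start plus 1, and peaks were assigned to windows by their midpoint. The span of an arm ran from its first to its last peak, and tests used the full windows within it. The crowded windows named in the text are counted from the first base of the arm. Peaks on 2L, 2R, 3L, 3R, X and 4 entered the comparisons between arms and of gaps. Those on U, Uextra and the 6 heterochromatin sequences were summarised apart and otherwise entered only the relation of score and width. Peaks per 100 kb window were compared by two-sided permutation of windows, X against 2L, 2R, 3L and 3R pooled and chromosome 4 against the same arms. Median widths and median scores were compared by two-sided permutation of peaks, each test with 100000 permutations, and Benjamini-Hochberg adjustment was applied within each family of tests. Neighbouring peaks are correlated, so that permuting single peaks gives p-values that can be too small. For this reason the differences of X and chromosome 4 from the autosome arms in median width and in scores also have a 95% interval from 2000 block bootstrap draws, in blocks of 500 kb, or of 100 kb for chromosome 4. Differences in peak number have a 95% interval from 2000 draws that resample single windows, which leaves correlation between windows out. Differences at the centromeric end of an assembled arm have no such interval. They were instead ranked among the contiguous, overlapping stretches of the same length that lay wholly within the rest of the arm. The relation of score and width was measured over the peaks of the whole list by Spearman's rho and by Pearson's r on log10 values. Gaps between neighbours were compared with 1000 random placements that kept the widths, the arm and the absence of overlap. An evenly spaced run was defined as successive start-to-start distances within 10% of their median, and 1000 permutations of the distances within arms gave its chance length. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

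Tested on simulated data, the comparison of windows gave p under 0.05 in 5% of 100 simulations without a difference for X (224 windows) and in 7% for chromosome 4 (12 windows). It detected 1.5 times as many peaks in 100% of simulations for X and in 47% for chromosome 4. The comparison of median widths gave p under 0.05 in 5% of 100 simulations without a difference, and in 100% with peaks 1.2 times as wide on X. The simulated windows and widths were drawn independently. These shares therefore do not show how correlation along an arm affects the p-values. The placement test found 5% of 20 random lists and 100% of 20 lists with peaks moved next to a neighbour.

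The comparisons of window counts, of width on X, of score with width and of neighbouring gaps were set before the data were examined, as were most alternatives (windows of 50 and 200 kb, peaks at or above the median score, the top 25% of scores, windows with at least 1 peak, joining for widths, and gaps of 500 and 2000 bp). The peaks named in the text follow a rule of the same date, namely the pair with the highest scores and the widest peak of each large arm and of chromosome 4, and the 3 longest stretches without a peak. Comparisons of score between arms, of width on chromosome 4, of the evenly spaced run and of the ends of arms were added later. Peak overlap with transcription start sites, gene lists, broad peaks at genes and promoter motifs were planned and not run, because the gene table used here is on release 6 and no genome or annotation of release 5 was used here.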

Results

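Trimethylation of lysine 4 of histone H3 (H3K4me3), a mark of the promoters of active genes, was mapped by chromatin immunoprecipitation and sequencing in white prepupae of Drosophila melanogaster, the short immobile stage that opens metamorphosis. The animals were of the Y cn bw sp strain. The labels list 2 libraries made with a rabbit polyclonal antibody against H3K4me3 and 2 libraries of input DNA, numbered as replicates within each kind. The values analysed here are the authors' peak list for the series as a whole, with 7743 peaks on 14 sequences of FlyBase release 5. Each peak has a position and a score from the authors' peak caller. The list gives no value per library, so no replicate error could be computed, the sequencing depth is unknown, and the background of the input libraries could not be set beside a peak. The comparisons below are therefore between chromosome arms and regions within 1 list, and their p-values refer to windows or peaks and not to replicate animals or cultures.

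H3K4me3 peaks were spread along all 6 chromosome arms, which held 7245 peaks or 93.6% of the list. Together these peaks covered 12313 kb, 10.2% of the arms between their first and last peaks. Arm 2R carried the most peaks for its length, at 66.6 per Mb, and arm 2L the fewest, at 55.2 per Mb. Values for 3L (57.2), chromosome 4 (59.0), X (60.8) and 3R (61.9 peaks per Mb) lay between these. The median peak of the whole list was 1227 bp wide (quartiles 541.5 and 2152.5 bp) and scored 110.4 (quartiles 22.7 and 253). The most crowded 100 kb window lay on 2L at 10200001 to 10300000 and held 31 peaks. On 3R the window at 1400001 to 1500000 held 28 peaks, as did the window at 15600001 to 15700000 on X.

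**Figure D1:**
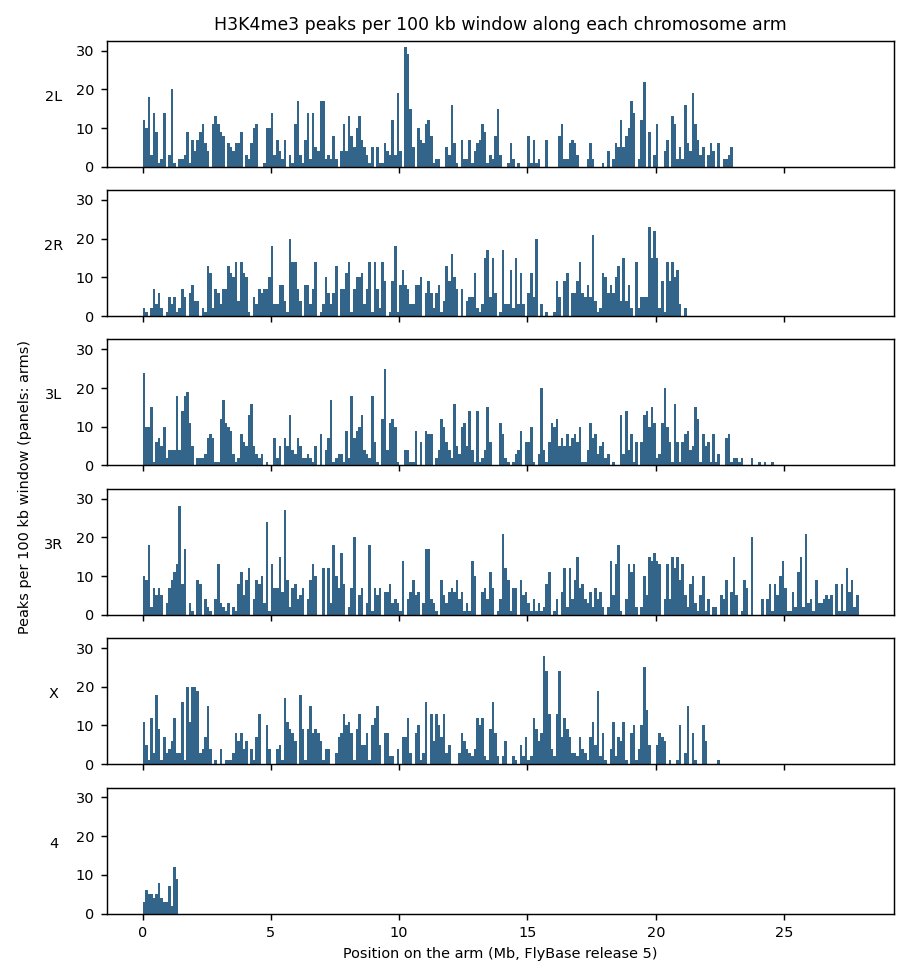
Number of H3K4me3 peaks in each 100 kb window (vertical axis) against position on the arm in Mb, FlyBase release 5 (horizontal axis), with 1 panel per chromosome arm. The tallest bar is the window of 31 peaks on 2L, and 44 windows of that arm hold no peak.

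The X chromosome, which is present once in males and as a pair in females, was compared with the 4 large autosome arms (2L, 2R, 3L and 3R) in the number of peaks. X carried 6.08 peaks per 100 kb window (SD 5.57, 224 windows) and the autosome arms 6.02 (SD 5.30, 963 windows). The difference of 0.0637 peaks per window had a 95% interval, from resampling single windows, from −0.713 to 0.870 (two-sided permutation test, adjusted p = 0.87). A difference in peak density between X and the autosome arms was thus not detected. With the peaks at or above the median score alone, the difference on X was −0.325 peaks per window, and with the top 25% of scores it was −0.0928, neither past the threshold.

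Chromosome 4, a small and largely heterochromatic chromosome, carried 4.92 peaks per 100 kb window (SD 2.54, 12 windows), against 6.02 on the large autosome arms. This difference of −1.10 (95% interval −2.47 to 0.408) did not pass the permutation test (adjusted p = 0.87). The tests used full windows, which leave out the end of the chromosome 4 span. Over its whole span chromosome 4 held 59.0 peaks per Mb, against 60.2 on the large autosome arms. The difference of −1.10 thus comes largely from the part left out. Over windows with at least 1 peak the difference was −2.03 (−3.34 to −0.596; permutation test, adjusted p = 0.28), an interval that excludes 0, and with 50 kb windows it was −0.412 (−2.05 to 1.74; permutation test, adjusted p = 0.85), per 100 kb in both cases. Leaving out empty windows kept all 12 of chromosome 4 and 834 of 963 on the autosome arms, so it could only widen the difference. Among the 25% of peaks with the highest scores, chromosome 4 had 0.333 per window and the autosome arms 1.62, a difference of −1.29 (−1.61 to −0.889; permutation test, adjusted p = 0.040). Among peaks at or above the median score the difference was −1.52 (−2.03 to −0.998), with an adjusted p = 0.14 that does not pass the permutation test. Both score-filtered tests leave out the same end of chromosome 4. This end holds its second-highest score, 291, at 1324644 to 1327522, so both differences are larger than over the whole span. With peaks 500 bp or less apart joined, an alternative chosen after the data were seen, the difference in number on chromosome 4 became 0.175. The comparisons in 100 kb windows rest on 12 windows of chromosome 4 and the one in 50 kb windows on 25.

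Peaks on X were narrower and scored lower at the median than those of the large autosome arms. The median width was 1201 bp for the 1363 peaks of X and 1363.5 bp for the 5806 peaks of the autosome arms, a difference of −162.5 bp (95% block bootstrap interval −253 to −52.0; two-sided permutation test, adjusted p = 0.0019). The median score, a comparison added after the data were seen, was 88.0 on X and 119.6 on the autosome arms, a difference of −31.7 (−49.3 to −15.1; permutation test, adjusted p = 0.00094). Peaks scoring under 50 made up 42.3% of the peaks on X and 36.8% of those on the autosome arms, a difference of 5.49 percentage points (2.41 to 8.79). The ratio of X to the autosome arms was 0.735 (0.605 to 0.869) for the median score. At the other percentiles computed the interval included 1, with ratios of 0.936 (0.813 to 1.08) at the 25th, 0.970 (0.859 to 1.05) at the 75th, 0.970 (0.920 to 1.03) at the 90th and 0.982 (0.913 to 1.03) at the 95th. The width difference on X was 2 bp among peaks at or above the median score (−81.0 to 148.5; permutation test, adjusted p = 0.98) and did not pass the test after joining of peaks 500 bp or less apart (−109 bp, adjusted p = 0.14). After the same joining the score difference on X was −22.0 (permutation test, p = 0.057).

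Chromosome 4 lacked the high-scoring peaks seen on the other arms. Its highest score was 305, whereas each of the large arms reached at least 572. The 75th percentile of its scores was 149 against 264 on the large autosome arms (ratio 0.563, 95% interval 0.375 to 0.718; permutation test, adjusted p = 0.00021), and the 90th percentile was 203 against 367 (ratio 0.553, 0.499 to 0.756; adjusted p = 3e-05). These percentiles were compared after the data were seen. The medians, 67.3 on chromosome 4 and 119.6 on the autosome arms, differed by −52.4, which did not pass the permutation test (p = 0.11), although the interval of −76.4 to −17.2 excluded 0. The median width of its 76 peaks was 1035.5 bp, against 1363.5 bp on the autosome arms. This difference of −328 bp did not pass the permutation test (p = 0.074), although its block bootstrap interval, −675 to −116 bp, excluded 0. Among peaks at or above the median score of the list, the 25 on chromosome 4 had a median width of 1453 bp and the 2995 on the autosome arms 2172 bp (permutation test, adjusted p = 0.027). Width rises with score over the list, so this comparison is not at equal score. Between scores of 100 and 200 the medians were 1453 bp on chromosome 4 (19 peaks) and 1634.5 bp on all arms. Between 200 and 300 they were 1528 bp (8 peaks) and 2133 bp, and above 300 chromosome 4 had 1 peak. After joining, where each stretch took the highest score of its peaks, the median score on chromosome 4 was 77.1 against 163 (permutation test, adjusted p = 0.027). Joining left 64 stretches from 76 peaks on chromosome 4 and 3773 from 5806 on the autosome arms.

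**Figure D2:**
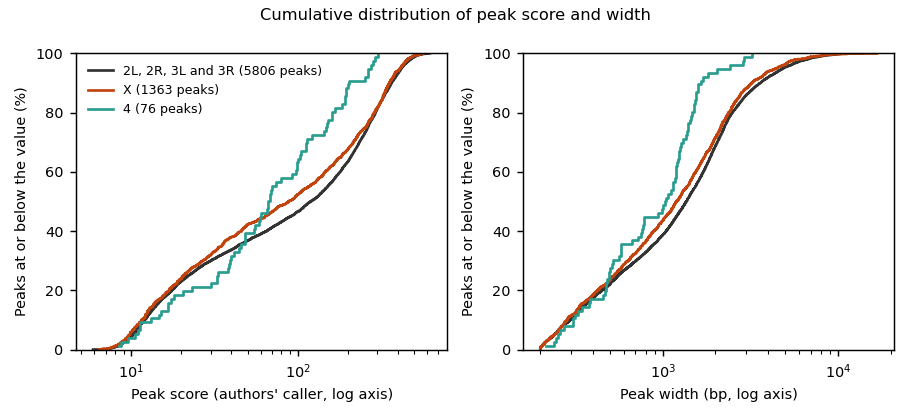
Cumulative share of peaks in percent (vertical axes) at or below a given score (left, log axis) or width in bp (right, log axis), for the 4 large autosome arms together, X and chromosome 4. The curve of chromosome 4 ends at a score of 305, and the X curve lies to the left of the autosome curve at the median score.

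High-scoring peaks were mostly wide. Across all 7743 peaks the score and the width had a Spearman's rho of 0.870 and a Pearson's r of 0.873 on log10 values (permutation p = 1e-05 for each, the smallest the permutations can give), where peaks are not independent replicates. Both values come from the same peak call, so they are not independent measures, and the relation may be partly built into the call. Within single arms rho ran from 0.764 on chromosome 4 to 0.888 on 3R. Over the 7245 peaks of the arms alone rho was 0.879, and among the 25% of peaks with the highest scores it was 0.30.

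The highest score of the list, 629, belonged to a peak of 1696 bp on 3L at 19825812 to 19827507. The next peak on 3L lay at 16570877 to 16580999, was also the widest of the arm at 10123 bp and scored 557. On 3R the peaks at 5460058 to 5463369 (3312 bp) and 14848369 to 14858429 (10061 bp) scored 625 and 609. The widest peak of 3R covered 12240 bp at 17851597 to 17863836 and scored 409. On 2L the peak at 18441809 to 18443294 reached 601 over 1486 bp, a width at the 54.6th percentile of its arm. The second score of 2L, 592, came from the 7190 bp peak at 10728980 to 10736169, and the widest peak of 2L, 12750 bp at 564050 to 576799, scored 366. On 2R the peak at 4781026 to 4790665 (9640 bp) scored 587 and the peak at 3162297 to 3165842 (3546 bp) scored 585. The widest peak of 2R covered 13889 bp at 10038359 to 10052247 with a score of 296. The widest peak of the whole list lay on X at 6178645 to 6195407, covered 16763 bp and had the highest score of that chromosome, 572. It was followed on X by a peak of 3091 bp at 1933283 to 1936373 with a score of 555. Chromosome 4 had its highest scores at 590480 to 591505 (1026 bp, 305) and at 1324644 to 1327522 (2879 bp, 291), and its widest peak, 3240 bp with a score of 266, at 1048503 to 1051742. The genes under these peaks are not given, since the gene table used here is on release 6 and coordinates were not carried between releases.

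Peaks lay in groups along the arms. Of the 7239 gaps between neighbouring peaks, 3292 (45.5%) were 1 kb or shorter, against a mean of 6.53% (central 95% range 5.98 to 7.10) in 1000 random placements of the same peaks on the same arms (one-sided permutation p = 0.001, the smallest these placements can give). Among peaks at or above the median score the share was 30.9%, against 3.30% in placements. Joining peaks 500 bp or less apart left 4726 stretches on the arms, of which 1613 (34.1%) held 2 or more peaks and 82 held 5 or more. The stretch with the most peaks, 11, lay on X at 509065 to 531927. On 3L the stretch at 7772 to 13473 joined 10 peaks, with a highest score of 11.2.

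**Figure D3:**
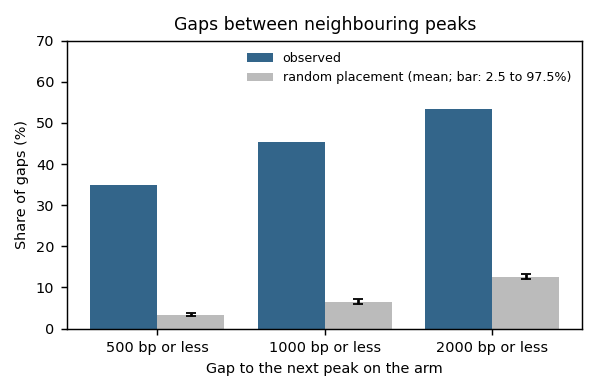
Share of gaps between neighbouring peaks, in percent (vertical axis), that are 500, 1000 or 2000 bp or shorter (horizontal axis), as observed and as the mean of 1000 random placements, with error bars over the central 95% of the placements. The observed shares are 34.8, 45.5 and 53.3%, and those of the placements 3.32, 6.53 and 12.6%.

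Near the base of 2L, 19 consecutive peaks followed one another at an almost constant distance, from 21451029 to 21542351. Their 18 spacings from start to start averaged 4992 bp (SD 140 bp over spacings, range 4623 to 5173). The median width in this run was 4363 bp, the scores lay between 204 and 297, and the peaks covered 86.5% of the 91.3 kb. A further 5 wide peaks with scores from 251 to 295 stood before it on 2L at 21416946 to 21440909, separated from the run by 10.1 kb. The starts of these wide peaks lay 4848 to 5124 bp apart, a spacing like that of the run. A peak of 243 bp scoring 12.6 lay among them. The longest run of such even spacings on any other arm had 6 spacings, and none of 1000 permutations of the spacings within arms gave one longer than 6. The run was singled out after the data were seen. At the outer ends of 3L and 2L peaks were weak and close together, with 21 peaks scoring 7.47 to 14.2 on 3L at 100 to 15789 and 6 peaks scoring 10.2 to 19.5 on 2L at 215 to 4417. Over the first 20 kb from base 1 of the arm, which is the outer end of 3L, 2L and X, 3L held 23 peaks scoring 7.19 to 16.2 (median 10.4), 2L held 7 scoring 10.2 to 114 (median 10.9) and X held 9 scoring 10.2 to 225 (median 70.4). In the same distance from base 1, 3R held 1 peak, scoring 170, and 2R and chromosome 4 held 0. A peak of 2R that starts at 18459 runs past this distance and was not counted. On these arms base 1 is the centromeric end, and their outer ends were not examined. These values were not tested against each other.

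**Figure D4:**
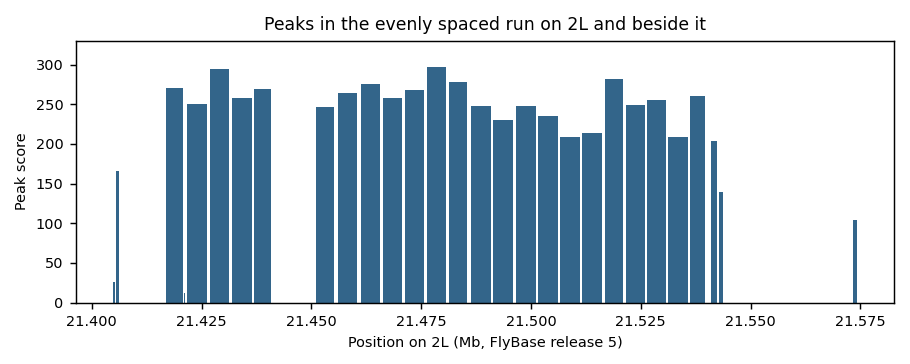
Peaks on 2L drawn to scale as blocks from start to end (horizontal axis, position in Mb on FlyBase release 5) with the score as height (vertical axis). The 19 blocks of the run score from 204 to 297 and begin on average 4992 bp apart.

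The 3 longest stretches without a peak lay outside the arms, at 1397992 to 4029443 (2631 kb) and 4029956 to 5629595 (1599.6 kb) on U and at 25249347 to 25952500 (703 kb) on Uextra. Both sequences are concatenations of fragments that the assembly does not place on an arm, so these distances are not distances along a chromosome. Within the arms, the longest stretch of each was also taken, a choice made after the data were seen. It measured 486 kb on 2L at 15771180 to 16256877, 470.3 kb on X at 21943547 to 22413859, 404 kb on 3L at 13508688 to 13912468 and 360.0 kb on 3R at 23791141 to 24151143. The longest on 2R, at 15719122 to 15999089, spanned 279.97 kb, and that on chromosome 4, at 231495 to 328766, 97.3 kb.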

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

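Peaks outside the 6 chromosome arms numbered 498, or 6.43% of the list, and entered the relation of score and width over the whole list but no comparison between arms. They are listed here as signal outside the main measurement, and their values were examined after the data were seen. Uextra, which joins fragments without a place in the assembly, held 419 of them, with a median width of 723 bp and a median score of 99.4. U held 28 peaks with a median score of 55.9, and the 6 heterochromatin sequences held 51 together with a median score of 74.98. Between scores of 100 and 200, the 142 peaks of Uextra had a median width of 771 bp and the 1204 peaks of the arms one of 1634.5 bp. In the same range 4.23% of the Uextra peaks and 66.4% of the arm peaks had a neighbour within 1 kb. The ends of the fragments can limit both the width of a peak and its neighbours on Uextra. These values are therefore not comparable with those of the arms. YHet, part of the Y chromosome, held 2 peaks, of 24.5 at most in score. No explanation was tested for these peaks.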

How the results depend on the processing

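The joined-peak comparisons of peak number and score, all alternatives for width on chromosome 4, the omission of the evenly spaced run and the relation of score and width on the arms alone were chosen after the data were seen. Of 28 alternative values for 8 results, 17 kept their direction and their side of the threshold. Keeping the peaks at or above the median score turned the X difference in number to −0.325 peaks per window and that in width to 2 bp, and took the width difference on chromosome 4 past the threshold, at −719 bp. With the top 25% of scores, the X difference in number turned to −0.0928 and the one in width shrank to −75.5 bp (adjusted p = 0.47, permutation), while chromosome 4 passed the threshold with −1.29 peaks per window. Joining peaks 500 bp or less apart turned the difference in number on chromosome 4 to 0.175, ended the X calls for width (−109 bp) and score (−22.0), and took chromosome 4 past the threshold for width (−648 bp) and score (−85.9). The cause of these changes was not tested, although each of these settings leaves fewer peaks. Joining merged a smaller share of the peaks on chromosome 4 (76 to 64) than on the autosome arms (5806 to 3773). With it the median width rose from 1035.5 to 1192 bp on chromosome 4 and from 1363.5 to 1840 bp on the autosome arms. The larger joined differences on chromosome 4 thus go with uneven joining. The share of close gaps stayed above its placements in every setting run, from 30.9% to 53.3%, and rho was 0.544 for peaks at or above the median score, 0.30 for the top 25% and 0.879 on the arms alone. No paired analysis was possible because the list has no values per library, and for the same reason no replicate could be left out. Also not run were arm lengths from the assembly, a further score column and all settings of the gene-based tests. The depth is unknown, so what it limits could not be measured here.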

Other observations

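Of the tests below, those of chance order in the evenly spaced run and of regional density were set before their results were seen, and all others were chosen after. Peak density at the centromeric end of the assembled arm was compared with the rest of each large arm. The heterochromatin sequences, which the list holds apart, did not enter. The list does not show how well reads could be placed near that end. In the 2 Mb of its span at the centromeric end, 3L held 1.35 peaks per 100 kb window against 6.12 on the rest of the arm (permutation test, adjusted p = 0.00055), 2R held 3.35 against 7.01 (adjusted p = 0.0050, permutation) and X 2.75 against 6.41 (adjusted p = 0.0088, permutation). Of the contiguous 2 Mb stretches wholly within the rest of the arm, which overlap one another, 0 of 206 on 3L, 0 of 172 on 2R and 0 of 185 on X had as few peaks. On 2L the values were 5.20 and 5.55 (permutation test, adjusted p = 0.80), but this part of 2L holds the evenly spaced run, without which they were 4.25 and 5.55 (permutation test, adjusted p = 0.31), and 72 of 190 such stretches had as few peaks, or 47 of 190 without the run. On 3R they were 8.15 and 6.04 (adjusted p = 0.12, permutation), and 208 of 239 stretches had as few peaks or fewer. The hypothesis that peaks are sparser there on every large arm passed the test on 3 of the 5 arms. On 2L no difference was detected, and on 3R the difference ran the other way without passing the test. Sparser peaks on every large arm were thus not shown.

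The evenly spaced run of 19 peaks on 2L is not accounted for by chance order of the spacings, since 0 of 1000 permutations gave as many as 18 even spacings. A candidate explanation is a tandem array of near-identical units, whose reads an aligner divides evenly among the copies. The scores in the run had a coefficient of variation of 0.107, below the lowest value of 7100 other stretches of as many peaks (0.132) and below their 5% value of 0.687, which goes with that explanation. Most peaks of the run were also alike in width, and score rises with width over the list, so the even scores do not single out that explanation. Similar marking of each copy would give the same evenness and was not tested apart. The replication-dependent histone genes of Drosophila are known as a tandem array near the base of 2L, but no release 5 annotation was used here to place them.

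The closeness of neighbouring peaks exceeds what regional density gives. Placements that kept the number of peaks in every 100 kb window had 12.1% of gaps at 1 kb or less (11.4 to 12.7), against 45.5% observed. Flanks in the weakest 25% of scores, split off peaks above the median score, are argued against as the source of most close gaps. Such pairs made up 23.5% of the close gaps (exact 95% interval 22.1 to 25%), and permuted scores gave 25.1% (23.8 to 26.6). The exact interval takes gaps as independent, although adjacent gaps share a peak. The test does not cover flanks that score above the weakest 25%. Nor does it cover wide regions that the caller cut into several strong or several weak peaks. In 33.0% of the close gaps both peaks scored above the median, against 25.1% (23.8 to 26.3) with permuted scores. Paired start sites of neighbouring genes, or a nucleosome-free gap within 1 promoter, may contribute and were not tested.

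The lower median score on X was set against a lower dose of X in males, for animals whose sex the labels do not give. If the score follows dose over its whole range, a dose effect should lower high and middling scores alike, but the X to autosome ratio was 0.970 at the 90th percentile and 0.735 at the median, a difference of 0.235 (95% interval 0.118 to 0.361), and 0.936 at the 25th. Input DNA of the same animals would carry the same dose, and how the input entered the call is not given. The score therefore need not follow dose, and these ratios do not decide for or against it. A splitting of X peaks into more weak pieces was examined by joining peaks 500 bp or less apart. Joining left 889 stretches from 1363 peaks on X and 3773 from 5806 on the autosome arms. This is about the same reduction, so the counts gave no sign of more splitting on X. The score difference went from −31.7 to −22.0 with joining, and its interval (−45.8 to 2.57) then included 0. As that interval also includes the value before joining, whether the pieces on X were weaker remains open. No biological explanation other than dose was examined.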
